A study of Mus musculus with 6 samples.

How the data were processed

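Gene expression was measured in 6 arrays of mouse embryonic salivary glands, 3 from untreated glands (controls 1 to 3) and 3 from glands exposed to TGF-β1 (TGF-β1 1 to 3). Per the labels' protocols, glands were taken from embryos at a stage written as T13, cultured for 72 hours and dissolved for extraction of total RNA, and biotin-labelled cRNA was made from 6 µg of it for Affymetrix arrays. The type of salivary gland and the dose of TGF-β1 are not given in the sources used here. Nor are the litters or cultures behind the replicate numbers and any date or batch of hybridisation. The arrays were placed in the 2 groups from their labels.

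The deposited values are log2 expression values per probe set, which the authors made with RMA per the submitters' processing notes; no version is given there. RMA subtracts background, brings the arrays to a common distribution and fits 1 value per probe set. The 6 deposited columns do not share 1 distribution: the interquartile range of control 3 was 2.05 on the log2 scale and that of the other arrays lay between 3.17 and 3.26. The values were used as deposited, with no filter on dim probe sets and no further scaling. Arrays carry no read depth, so the number of arrays limits the precision.

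Of the 22206 probe sets of the table, 19572 had exactly 1 gene symbol in the platform annotation used here, 0 had several and 2634 were unnamed here. All 19572 Entrez gene identifiers were found in the gene table of the mouse reference, with 0 differing symbols. Where a gene had more than 1 probe set, the one with the highest mean over the 6 arrays stood for it, which left out 67 probe sets and gave 19505 genes. No genome build is named in the sources used here and no coordinates were used.

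The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), with all 6 arrays, the group as the only term and Benjamini-Hochberg adjustment over the 19505 genes. A gene passed at an adjusted p under 0.05. A difference is the mean of the TGF-β1 arrays minus the mean of the controls on the log2 scale. The same fit with array weights (arrayWeights, which estimates the reliability of each array from its residuals over all genes) was set as an alternative before the data were examined. Its estimation stopped before reaching its convergence tolerance, and the weights are then treated as known, which makes its p-values smaller than they should be. In the report, a gene is said to have risen or fallen where it passed in the array-weighted fit, because the unweighted fit passed 0 genes; that choice was made after the data were seen. Fits without control 3, without control 3 but with array weights, and without control 3 and TGF-β1 3 were run beside them, the last 2 chosen after the data were seen.

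The 30 gene lists (pathways, cell types of the gland and cell types a cultured gland can carry along) were written before the data were examined and hold 700 distinct measured genes, of which 23 are in more than 1 list. They were tested with limma's camera with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation, fry, and counts of members that passed over all genes and adjusted over the list alone stand beside it. With an estimated correlation, camera also limits its test to the residual degrees of freedom (4 with 6 arrays, 3 without control 3). Its larger p-values therefore do not measure correlation between genes alone. A list median for 1 array is the median over the list's genes of the log2 value minus the mean of controls 1 and 2; controls 1 and 2 therefore mirror each other around 0.

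Genes were named by a rule set before the data were examined. It took the 12 genes per direction with the largest change among those that passed with non-overlapping groups, filled up with those of smallest p where fewer than 12 passed. It left out predicted genes, receptors of smell and small RNA genes. It added up to 3 members per list and direction that passed, or the 1 of smallest p where none passed, and 26 fixed symbols, of which 25 were measured. The unweighted fit passed 0 genes, so its named genes are those of smallest p. The same rule was applied to the array-weighted fit after the data were seen, and some of the genes it gives are named.

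The alternatives were quantile normalization, median centring, a filter that left out the lowest 33.3% of genes by mean value and kept 13003, the mean of the probe sets of a gene, all probe sets one by one, a trended and robust prior, the replicate number as a block, each array left out in turn, and stricter thresholds. The fits were tested on simulated data with 19505 genes drawn independently, of which 200 were changed. Control 3 and TGF-β1 3 each had a spread of their own, and the other 4 arrays shared 1 spread per gene. The unweighted fit recovered 0% of genes changed by 1 or by 2 log2 units and 54.5% of those changed by 4, with 0 calls among unchanged genes. The array-weighted fit recovered 100% at each size, with 40 calls among unchanged genes, which is more than its threshold allows. The fit without control 3 and TGF-β1 3 recovered 97.0% at 1 log2 unit and 100% at 2 and at 4. It made 31 calls among unchanged genes, which is also more than its threshold allows. In 20 draws with no changed gene, the array-weighted fit called a median of 12.5 and at most 23 genes, and the unweighted fit 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.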

Results

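Salivary glands of mouse embryos were kept in culture for 72 hours, untreated or with TGF-β1, a secreted growth factor that signals through its receptors and Smad proteins, and their transcripts were measured on 6 arrays, 3 per group. The study asked what exposure to TGF-β1 does to the glands. The deposited table held log2 values of 22206 probe sets, from which 19505 genes were compared. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

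Control 3 stood apart from the other arrays. Over all genes, its Pearson correlation with the others lay between 0.550 and 0.601, while controls 1 and 2 and TGF-β1 1 and 2 correlated with each other at 0.974 to 0.990. TGF-β1 3 correlated with those 4 arrays at 0.948 to 0.953. Genes that every cell uses were low in control 3: Actb, which encodes β-actin, was at 8.91 against 12.70 to 13.34 in the other arrays, Gapdh, a glycolytic enzyme, was at 6.21 against 11.87 to 11.98, and the median of 60 ribosomal protein genes was 8.43 against 12.43 to 12.80. The first principal component took up 81.9% of the variance and set control 3 apart, the second took up 10.2% and set TGF-β1 3 apart, and the third took up 5.13% and separated the remaining arrays by group. Without control 3, the first component (56.0%) set TGF-β1 3 apart and the second (28.2%) separated the groups.

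**Figure D1:**
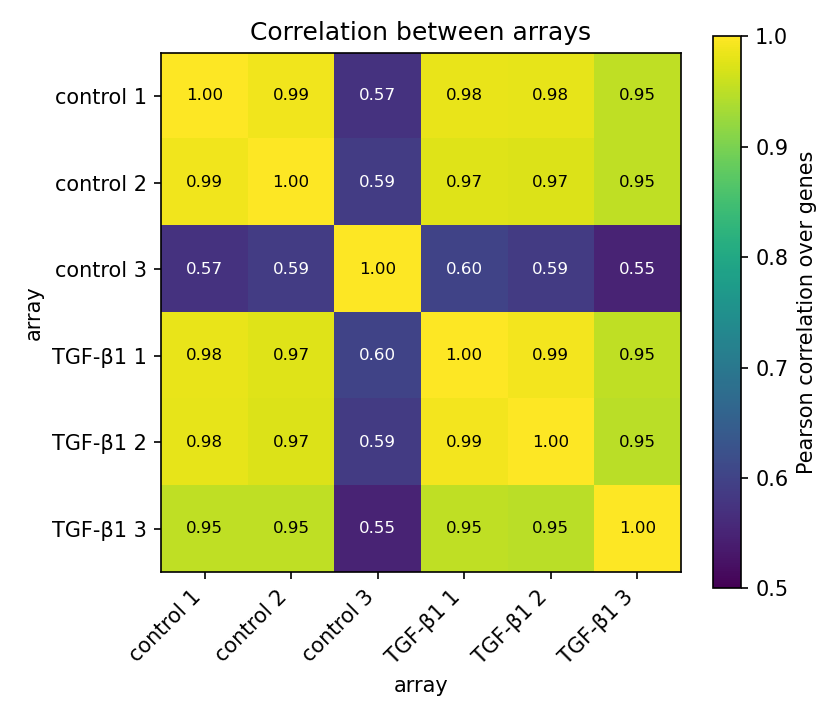
Pearson correlation over 19505 genes between each pair of the 6 arrays (both axes list the arrays; colour and numbers give the correlation). Control 3 correlates with the others at 0.550 to 0.601, and all pairs without it lie at 0.948 or above.

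Bpifa2 (Entrez gene 19194), an abundant salivary protein, had the smallest p between the groups. It averaged 13.42 ± 0.41 in the TGF-β1 arrays and 6.19 ± 1.52 in the controls (log2 value, SD, n = 3 each), a difference of 7.24 ± 0.73 (SE). Cnmd, a matrix protein of cartilage, had the next smallest and was higher by 3.27 ± 0.42. Smgc, a secreted protein of the neonatal submandibular gland whose gene shares its locus with a mucin gene, was higher by 4.71 ± 0.72, Pip, a secretory protein, by 4.45 ± 0.71, and Lpo, the peroxidase of saliva, by 4.09 ± 0.69. Slc4a4, a sodium bicarbonate cotransporter, differed by -1.64 ± 0.31, Abca6, a lipid transporter, by -2.28 ± 0.54, and Pfkfb3, a regulator of glycolysis, by -1.35 ± 0.33. All 8 genes had non-overlapping groups, as did 2259 genes (11.6%) in all, where chance gives 10%.

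None of these differences passed in limma's unweighted fit of the 6 arrays, which called 0 of 19505 genes. The smallest adjusted p was 0.397, for Bpifa2, and the other genes of smallest p were at 0.776. At an unadjusted p under 0.05 there were 389 genes, 285 higher and 104 lower in the TGF-β1 arrays, and the median difference over all genes was -0.14, against 0.01 without control 3. Quantile normalization moved that median to -0.10, and the filter on dim genes to 0.09. With array weights, which gave control 3 a weight of 0.0338, TGF-β1 3 one of 0.398 and the others 1.65 to 4.52, 1342 genes passed, 672 higher and 670 lower, with 3997 at an unadjusted p under 0.05. In simulated arrays with no changed gene, their genes drawn independently, that fit called up to 23 genes. Genes of real arrays can deviate together, so 23 is no upper limit for false calls here. Without control 3, 0 genes passed in the unweighted fit (1487 at an unadjusted p under 0.05) and 544 with array weights. Without control 3 and TGF-β1 3, 505 passed, 223 higher and 282 lower. Of these 505, 219 of the higher and 265 of the lower genes were among the 1342, and none was called in the opposite direction; the 2 fits rest largely on the same 4 arrays.

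Of the 24 measured acinar and secretory markers, 14 rose in the array-weighted fit, 0 fell and 10 did not pass; adjusted over the list alone, 16 rose. Of the 14, 11 also passed without control 3 and TGF-β1 3. In the unweighted fit 0 passed over all genes and 8 passed adjusted over the list alone, namely Bpifa2, Bhlha15, Smgc, Pip, Lpo, Spdef, Ano1 and Kcnn4. With array weights Bpifa2 rose by 7.87 ± 0.57 (SE, adjusted p = 8.69e-05), Lpo by 5.02 ± 0.50 and Smgc by 4.86 ± 0.46. Bhlha15, a transcription factor of secretory cells, rose by 2.95 ± 0.26 (adjusted p = 1.89e-04), Spdef, another such factor, by 1.88 ± 0.17, Ano1, the calcium-activated chloride channel of acinar cells, by 2.18 ± 0.17, Kcnn4, a calcium-activated potassium channel, by 2.50 ± 0.26, and Aqp5, the apical water channel, by 1.09 ± 0.13 (adjusted p = 0.0010).

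Other genes of smallest p in this direction were Creb3l4, a transcription factor related to secretory proteins, which rose by 2.82 ± 0.29, Pglyrp1, an antibacterial secreted protein, by 2.78 ± 0.28, Esp8, of a family of peptides secreted by exocrine glands, by 2.88 ± 0.21, Elapor1, an endosome and lysosome protein, by 3.45 ± 0.37, Chn2, a Rac-regulating protein, by 2.19 ± 0.16, and Mlph, a linker of vesicles to myosin, by 1.82 ± 0.17. The controls also differed from each other in these genes, Bpifa2 being at 7.68 in control 1, 4.65 in control 2 and 6.22 in control 3, and Smgc at 6.25, 4.60 and 5.65; both values of control 2 lay under that array's lower quartile of 5.13. No measure of background is given, so the size of the differences of these 2 genes is uncertain if control 2 held neither transcript. With array weights, where control 2 had a weight of 4.52, they were 7.87 and 4.86, against 7.24 and 4.71 without. In control 3, Bpifa2, Smgc, Pip and Bhlha15 were at 5.65 to 6.43, below its median over all probe sets (6.80), and Smgc, at 5.65, lay below its lower quartile of 5.79 as well. Camera gave the list an adjusted p of 4.89e-18 with its preset correlation and an adjusted p of 0.0571 with an estimated correlation (adjusted p = 0.141 with array weights). The list median in control 3 (0.23) lay near that of control 1 (0.17), and the 3 TGF-β1 arrays were at 0.99 to 1.39.

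Some epithelial genes and some genes of dividing cells rose with array weights. Of 38 epithelial identity and junction genes, 17 rose, 0 fell and 21 did not pass (29 rose adjusted over the list alone). Cldn1 and Cldn3, tight junction proteins, rose by 1.89 ± 0.19 (adjusted p = 3.47e-04) and 1.47 ± 0.19, Ehf, an epithelial transcription factor, by 1.71 ± 0.27, Prss8, an epithelial membrane protease, by 1.16 ± 0.20, and Epcam, an adhesion molecule of epithelial cells, by 1.01 ± 0.20. Only 2 of the 17 also passed without control 3 and TGF-β1 3, Ehf (adjusted p = 0.0618), Prss8 (0.119) and Epcam (0.124) not among them. Cdh1, which encodes E-cadherin, differed by 0.69 ± 0.23 (adjusted p = 0.104). Of 39 proliferation genes, 18 rose, 0 fell and 21 did not pass (30 rose adjusted over the list alone). Mki67, a marker of cycling cells, rose by 1.06 ± 0.21 (adjusted p = 0.0117), the mitotic cyclin Ccnb2 by 0.95 ± 0.14, Birc5, an inhibitor of apoptosis used in mitosis, by 0.82 ± 0.15, and the centromeric histone Cenpa by 0.79 ± 0.14. Of these 18, 6 also passed without control 3 and TGF-β1 3. Mki67 was at 10.45 in TGF-β1 3, between 10.29 and 10.52 in controls 2 and 1. In the unweighted fit 0 members of either list passed, over all genes or adjusted over the list alone.

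Control 3 lay far below the others for both lists, with medians of -1.23 for the epithelial and -1.44 for the proliferation list. Without it the list medians were 0.51 and 0.57. Controls 1 and 2 also differed from each other in the epithelial list, at 0.22 and -0.22, against 0.61 to 0.65 in the TGF-β1 arrays. Ehf was at 10.63 and 9.54 and Epcam at 9.63 and 8.93 in controls 1 and 2. The array-weighted fit gave the lower control 2 a weight of 4.52 and control 1 one of 1.65, and its epithelial median was 0.70. For the proliferation list controls 1 and 2 were at -0.04 and 0.04, and the TGF-β1 arrays at 0.36 to 0.60. With the preset correlation camera gave the epithelial list an adjusted p of 1.57e-14 and the proliferation list one of 7.16e-20. With an estimated correlation their adjusted p were 0.594 and 0.619, and without control 3 they were 0.306 and 0.182.

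**Figure D2:**
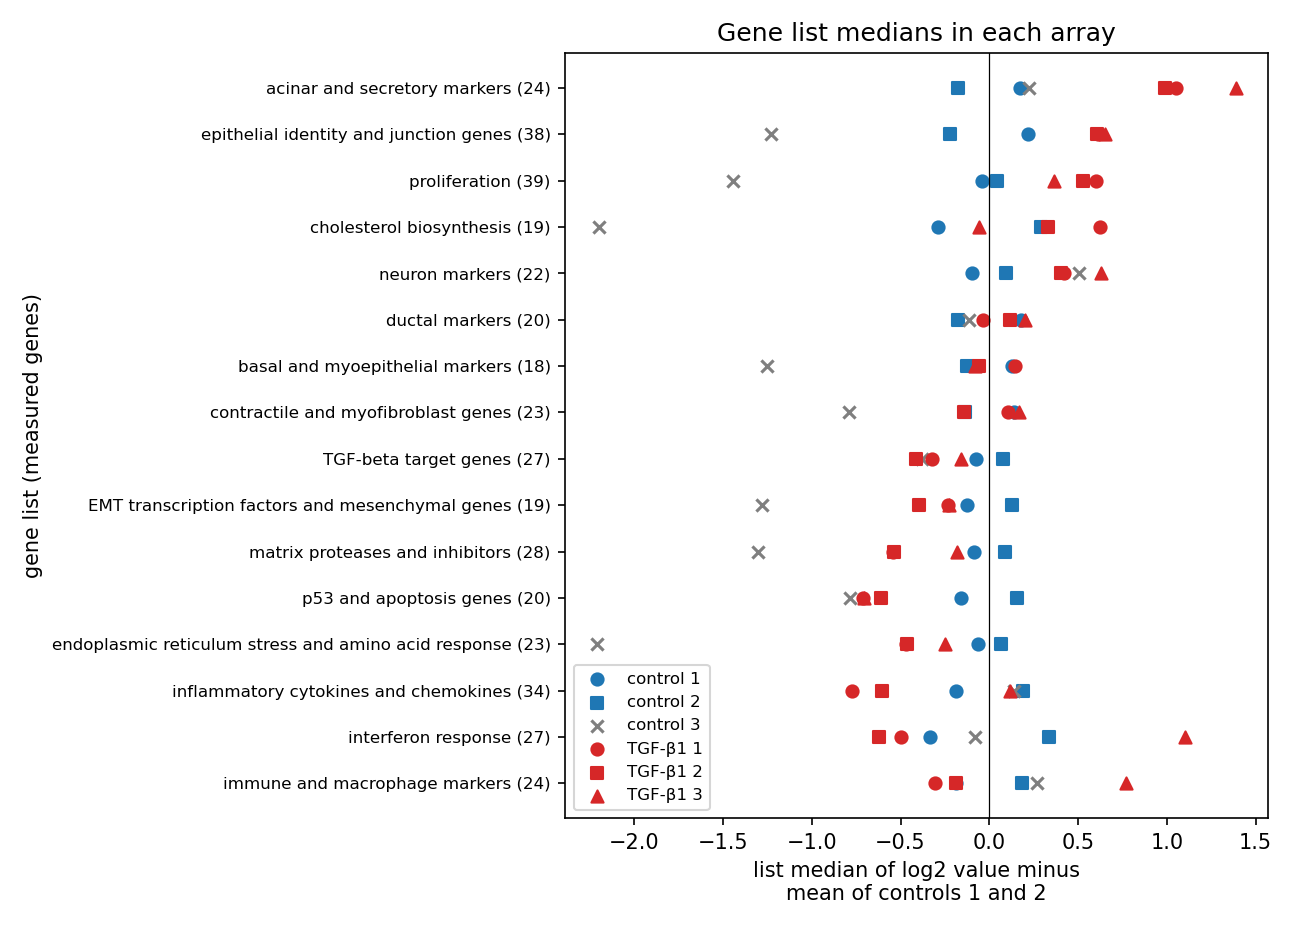
Median over the genes of 16 gene lists (number of measured genes in brackets) of each array's log2 value minus the mean of controls 1 and 2, 1 symbol per array. Acinar and secretory markers are at 0.99 to 1.39 in the TGF-β1 arrays and at most 0.23 in the controls, control 3 lies at -2.21 for endoplasmic reticulum stress genes, and TGF-β1 3 lies at 1.10 for interferon response genes. For the acinar list, control 3 had bright members such as Kit lower and dim ones such as Gal higher than controls 1 and 2.

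Several known targets of TGF-β were lower in the TGF-β1 arrays, and none passed as higher over all genes. Of 27 measured TGF-β target genes, 0 rose with array weights, 10 fell and 17 did not pass; adjusted over the list alone 1 rose and 11 fell. Tnfaip6, a hyaluronan-binding protein also induced in inflammation, fell by 2.68 ± 0.28 (adjusted p = 3.77e-04), Timp1, an inhibitor of matrix proteases, by 1.82 ± 0.28, Adam12, a membrane metalloprotease, by 1.41 ± 0.19, and Junb, a subunit of the AP-1 transcription factor, by 1.37 ± 0.17. Timp1 was at 9.53 in TGF-β1 3, above controls 1 and 2 (9.11 and 9.27), and at 7.42 and 6.99 in TGF-β1 1 and 2; Tnfaip6 was at 8.79 in TGF-β1 3 and at 6.77 and 6.49 in the other 2, against 9.19 and 9.59 in controls 1 and 2. In the unweighted fit without control 3 they differed by -1.21 (adjusted p = 0.842) and -2.04 (adjusted p = 0.528). Smad7, the inhibitory Smad of the pathway, differed by -0.30 ± 0.17 (adjusted p = 0.391), and Ccn2, a matricellular protein, by -0.17 ± 0.14 (adjusted p = 0.571). Of the 22 ligands, receptors and Smads, 1 passed and 21 did not. Tgfb2 fell by 1.62 ± 0.18 (adjusted p = 5.06e-04). With array weights Tgfb1 differed by -0.39 ± 0.20, Tgfb3 by -0.06 ± 0.19, Tgfbr1 by 0.06 ± 0.19, Tgfbr2 by -0.49 ± 0.20, Smad3 by -0.35 ± 0.15, and Eng, a co-receptor, by 0.52 ± 0.24. In the unweighted fit Tgfb1, Tgfb3 and Tgfbr2 had the opposite sign (0.27, 0.67 and 1.16). Of 22 BMP and Id genes, 1 rose, Id2, by 1.01 ± 0.17, and 3 fell, among them Id3 by 1.35 ± 0.25. Tgfb2, Id2 and 9 of the 10 fallen targets also passed without control 3 and TGF-β1 3, and 0 of the 3 fallen BMP and Id genes (Id3 adjusted p = 0.129). Adjusted over the list alone, these counts were 0 risen and 1 fallen for the ligands list and 1 and 3 for the BMP list.

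The targets list had a camera adjusted p of 0.129 unweighted and 6.48e-07 with array weights, and with an estimated correlation an adjusted p of 0.619 and 0.141. Its median was -0.38 in control 3 and -0.41 to -0.16 in the TGF-β1 arrays. Without weights, 0 of its members passed adjusted over the list alone.

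Of 28 matrix proteases and inhibitors, 0 rose with array weights, 11 fell and 17 did not pass (15 fell adjusted over the list alone). Mmp2, a gelatinase, fell by 1.70 ± 0.20 (adjusted p = 8.81e-04) and Adamts5, an aggrecanase, by 1.49 ± 0.19. Of 39 collagen and fibrous matrix genes, 2 rose and 4 fell. Cthrc1, a secreted protein of matrix-forming cells, rose by 1.84 ± 0.19 (adjusted p = 4.29e-04), Fn1, which encodes fibronectin, fell by 0.62 ± 0.15 (adjusted p = 0.0276; adjusted p = 0.151 without control 3 and TGF-β1 3), and Col1a1 differed by -0.35 ± 0.18 (adjusted p = 0.331). Of 18 genes of collagen processing, 0 rose and 2 fell, and the one of smallest unweighted p, Adamts14, a procollagen protease, differed by -0.33 ± 0.26. Of 23 basement membrane and integrin genes, 1 rose and 2 fell, and Itgav, the αv integrin subunit, differed by -0.38 ± 0.14 (adjusted p = 0.151). Adjusted over the list alone, 3 rose and 6 fell among the collagens, 0 and 4 in collagen processing, and 2 and 3 in the basement membrane list. With control 3 and TGF-β1 3 left out, 8 of the 11 fallen proteases and inhibitors also passed, 1 risen and 1 fallen collagen gene, and 0 members of the other 2 lists. Camera gave the protease list an adjusted p of 0.475 unweighted and 8.74e-11 with array weights, and with an estimated correlation an adjusted p of 0.872 and 0.178. Control 3 was at -1.30 for this list.

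Few contractile and mesenchymal genes passed. Of 23 contractile and myofibroblast genes, 2 rose and 2 fell with array weights. Acta2, smooth muscle actin, rose by 1.498 ± 0.354 (adjusted p = 0.0263) and Cnn1, a smooth muscle calponin, by 1.70 ± 0.41, but neither passed without control 3 and TGF-β1 3, where Acta2 differed by 1.06 (adjusted p = 0.336) and Cnn1 by 1.11 (adjusted p = 0.332). Acta2 was at 11.68 in control 1 and 9.95 in control 2, against 11.53 to 12.01 in the TGF-β1 arrays. Cnn2 fell by 0.52 ± 0.14 (adjusted p = 0.117 without those 2 arrays). Camera called this list higher in the unweighted fit (adjusted p = 0.0481), with an adjusted p of 0.619 with an estimated correlation and of 0.273 with array weights, and control 3 was at -0.79. Of 19 genes of epithelial to mesenchymal transition, 0 rose and 3 fell, among them the transcription factor Twist1, by 0.96 ± 0.20 (adjusted p = 0.0135), which did not pass without control 3 and TGF-β1 3 (adjusted p = 0.0716); 1 of these 3 and 0 contractile genes also passed there. Snai1 differed by -0.22 ± 0.15, Snai2 by -0.36 ± 0.18, Zeb1 by -0.40 ± 0.16, Twist2 by -0.42 ± 0.16, Vim by -0.45 ± 0.19 and Cdh2 by 0.17 ± 0.16, and none of these passed. Control 3 was at -1.28 for this list, whose median was 0.20 unweighted and -0.39 with array weights (camera adjusted p = 8.31e-04; adjusted p = 0.343 with an estimated correlation). Adjusted over the list alone, 5 rose and 3 fell among the contractile genes and 0 and 3 in the transition list.

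Growth factors of branching changed in opposite directions. Of 33 genes of FGF, ectodysplasin and branching signals, 4 rose with array weights, 3 fell and 26 did not pass (7 rose and 8 fell adjusted over the list alone). Fgf10 and Fgf7, mesenchymal growth factors that act on gland epithelium, fell by 1.57 ± 0.21 (adjusted p = 0.0016) and 1.29 ± 0.18, while Fgf1 rose by 1.79 ± 0.24, Sox10, a transcription factor of distal gland epithelium, by 1.13 ± 0.18 and Sox9, another such factor, by 0.68 ± 0.15 (adjusted p = 0.0683 without control 3 and TGF-β1 3, where 2 risen and 2 fallen genes of the list also passed). Fgf10 was at 5.54 in control 3, 9.07 and 9.63 in the other controls and 7.81 to 8.04 in the TGF-β1 arrays, so that its unweighted difference was -0.13 ± 1.00.

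**Figure D3:**
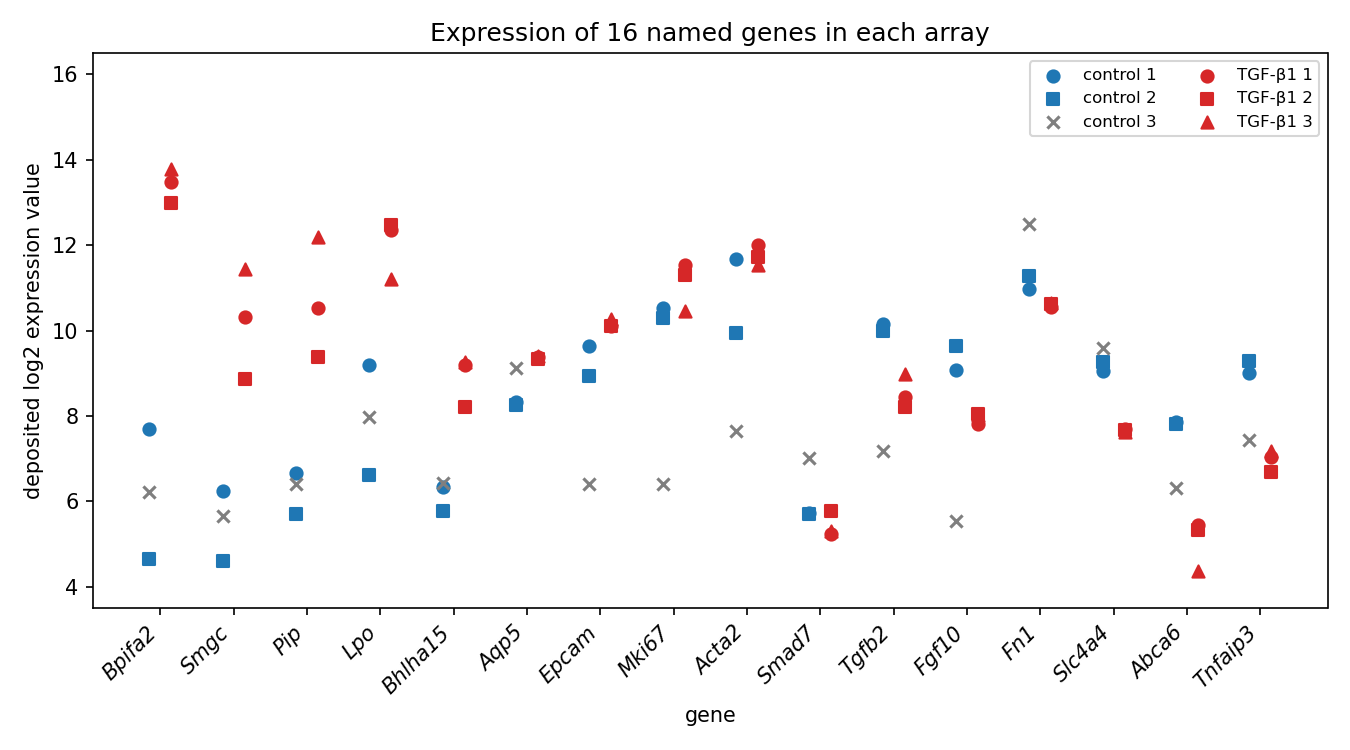
Deposited log2 expression value (vertical axis) of 16 named genes (horizontal axis) in each of the 6 arrays, controls in blue or, for control 3, grey, and TGF-β1 arrays in red. Bpifa2 lies at 12.99 to 13.79 in the TGF-β1 arrays and at 4.65 to 7.68 in the controls, while for Fgf10, Tgfb2, Epcam and Mki67 control 3 lies below all other arrays.

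Some genes of damage, stress and inflammation fell with array weights. Of 20 p53 and apoptosis genes, 10 fell and 1 rose (15 fell adjusted over the list alone). Cdkn1a, the p21 cell cycle inhibitor, fell by 2.59 ± 0.39 (adjusted p = 0.0029), Eda2r, a p53-induced receptor, by 2.22 ± 0.23 and Pmaip1, a pro-apoptotic protein, by 1.25 ± 0.20, while Sesn1, a stress-induced sestrin, rose by 0.93 ± 0.17. Cdkn1a was at 10.95 in TGF-β1 3, near controls 1 and 2 (11.03 and 11.62), and at 8.32 and 9.46 in TGF-β1 1 and 2; its unweighted difference was -0.21, and -1.75 without control 3 (adjusted p = 0.658). Of 34 inflammatory cytokines and chemokines, 14 fell and 0 rose (17 fell adjusted over the list alone), with Tnfaip3, an inhibitor of NF-κB signalling, down by 2.27 ± 0.17 (adjusted p = 8.69e-05), the cytokine Il6 by 2.19 ± 0.27, the adhesion molecule Icam1 by 1.36 ± 0.17 and the chemokine Cxcl2 by 1.17 ± 0.15. Of 23 genes of endoplasmic reticulum stress and amino acid response, 9 fell and 0 rose (14 fell and 1 rose adjusted over the list alone), among them the cystine transporter Slc7a11, by 2.67 ± 0.27 (adjusted p = 3.47e-04), the transcription factor Ddit3 by 1.91 ± 0.30 and the pseudokinase Trib3 by 1.32 ± 0.18. Ddit3 was at 11.57 in TGF-β1 3, within the range of controls 1 and 2 (11.26 and 11.83), and at 9.44 and 9.98 in TGF-β1 1 and 2; its unweighted difference was 0.12, and -1.21 without control 3 (adjusted p = 0.781). Of 25 immediate early and stress genes, 9 fell, among them Egr3 by 0.78 ± 0.16, and 1 rose, Nr4a2, by 1.18 ± 0.23 (15 fell and 1 rose adjusted over the list alone). Nr4a2 was at 9.74 in TGF-β1 3, between controls 2 and 1 (9.61 and 10.14). With both distant arrays (control 3 and TGF-β1 3) left out, 4 of the 10 fallen p53 genes, 8 of 14 inflammatory, 6 of 9 endoplasmic reticulum and 7 of 9 immediate early genes also passed, as did Sesn1 and Nr4a2, while Pmaip1 (adjusted p = 0.0544) and Egr3 (0.0571) did not.

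In the unweighted fit camera called the p53 list lower (adjusted p = 0.0273; adjusted p = 0.619 with an estimated correlation) and did not call the inflammatory (0.0599), endoplasmic reticulum (0.363) and immediate early (0.136) lists. With array weights their adjusted p were 6.10e-11, 4.89e-10, 2.78e-06 and 2.57e-08, in that order, and with an estimated correlation adjusted p = 0.178, 0.343, 0.343 and 0.227. Control 3 was at -0.79, 0.14, -2.21 and -2.41 for these lists, and TGF-β1 3 was at 0.12 for the inflammatory list, against -0.78 and -0.60 in TGF-β1 1 and 2. The immune and macrophage markers, none of which passed, had a median of -0.31 with array weights (camera adjusted p = 0.0019; adjusted p = 0.614 with an estimated correlation). For the endoplasmic reticulum list, median, mean and test were positive in the unweighted fit and negative with array weights.

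Interferon, sterol and glycolysis genes gave mixed results. Of 27 interferon response genes, 3 fell with array weights, among them Gbp2, a guanylate-binding protein, by 0.89 ± 0.15, and 0 rose; the list median was 1.10 in TGF-β1 3 and -0.50 and -0.62 in TGF-β1 1 and 2. Of 19 genes of cholesterol synthesis, 4 rose and 0 fell, among them Nsdhl by 1.02 ± 0.23 and Ebp by 0.77 ± 0.17, both enzymes of the pathway. Of 26 hypoxia and glycolysis genes, 2 rose and 3 fell, Egln3, an oxygen-sensing hydroxylase, rising by 1.19 ± 0.21. Without control 3 and TGF-β1 3, 1 of the 3 fallen interferon genes, 0 of the 4 risen cholesterol genes (Nsdhl adjusted p = 0.0829, Ebp 0.0594), 0 of the 2 risen hypoxia genes (Egln3 0.0945) and 2 of the 3 fallen ones also passed. Camera called the cholesterol (adjusted p = 7.46e-08) and hypoxia (adjusted p = 0.0041) lists higher in the unweighted fit. With an estimated correlation their adjusted p were 0.619 and 0.627, and control 3 was at -2.20 and -1.63. With array weights the hypoxia list was not called (adjusted p = 0.526). Adjusted over the list alone, 0 rose and 7 fell in the interferon list, 4 and 0 in the cholesterol list, and 4 and 6 in the hypoxia list.

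Markers of other gland cells went both ways with array weights, and most of the neuron markers that passed rose. Of 20 ductal markers, 3 rose and 1 fell, with Elf5, a transcription factor of luminal cells, up by 2.24 ± 0.25 (adjusted p = 5.70e-04); the list median (-0.04) and its mean and camera's direction (0.19, higher) differed in sign in the unweighted fit. Of 18 basal and myoepithelial markers, 2 rose, among them the homeobox gene Barx2 by 1.16 ± 0.20, and 1 fell, Dst, a linker of the cytoskeleton, by 0.99 ± 0.14. Krt5 differed by -0.49 ± 0.21, Krt14 by -0.59 ± 0.24 and Krt19 by -0.56 ± 0.36, and none of these passed; without weights they had the opposite sign (0.07, 0.83 and 0.90). Of 22 neuron markers, 7 rose and 1 fell, among the risen Rtn1, an endoplasmic reticulum protein of neurons, by 1.07 ± 0.18, Ret, a receptor of neurotrophic factors, by 0.77 ± 0.14, and Tubb3, a neuronal tubulin, by 0.66 ± 0.16. Without control 3 and TGF-β1 3, 2 of the 7 risen neuron markers also passed, Rtn1 (adjusted p = 0.0326) and Ret (0.0468), but not Tubb3 (0.0934), and 0 fallen ones; 2 risen ductal and 1 fallen basal marker also passed, but not Barx2 (0.103). Adjusted over the list alone, 3 ductal markers rose and 2 fell, 2 basal markers rose and 3 fell, and 8 neuron markers rose and 1 fell.

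In the remaining lists few members passed with array weights. These were 1 risen (Sox2, by 0.91 ± 0.20) and 2 fallen of 14 Schwann cell and glia markers, 2 fallen of 22 endothelial markers, Kdr and Cd34, by 1.35 ± 0.19 and 1.00 ± 0.20, 2 fallen of 10 erythroid markers, among them Hba-x by 0.68 ± 0.15, 2 risen of 23 cartilage and bone markers, and 1 risen of 14 adipocyte markers, Scd1, a fatty acid desaturase also active outside fat, by 1.32 ± 0.16. When control 3 and TGF-β1 3 were left out, 1 fallen Schwann cell marker, 1 endothelial, 0 erythroid, 1 cartilage and 1 adipocyte marker also passed, but not Sox2 (adjusted p = 0.119), Cd34 (0.114) and Hba-x (0.148). Cnmd rose by 3.35 ± 0.30 (adjusted p = 2.06e-04), and was the 1 cartilage marker that passed adjusted over the list alone in the unweighted fit. None of 24 immune and macrophage markers and none of 27 skeletal muscle markers passed, and the members of smallest unweighted p, Coro1a and Ttn, differed by -0.28 ± 0.14 and -0.61 ± 0.18. Many members of these lists were dim. Above the median of both TGF-β1 1 and 2 lay 9 of the 24 immune, 5 of the 27 muscle, 2 of the 22 endothelial and 2 of the 10 erythroid markers. The lack of calls therefore does not show that these cell types were unchanged. The endothelial gene of smallest unweighted p, Tie1, differed by -0.05 ± 0.16. Adjusted over the list alone, 2 Schwann cell markers rose and 2 fell, 2 endothelial and 2 erythroid markers fell, 3 cartilage markers rose and 1 fell, 1 adipocyte marker rose, and 0 immune and 0 muscle markers passed. The acinar and cartilage lists were the only ones in the unweighted fit with a member that passed adjusted over the list alone. In the unweighted fit camera called the basal list (adjusted p = 0.0448), the neuron list (0.0125) and, as lower, the erythroid list (0.0239). With an estimated correlation their adjusted p were 0.627, 0.619 and 0.627, and control 3 was at -1.25, 0.51 and 1.02. With an estimated correlation 0 of the 30 lists passed in any of the unweighted, array-weighted and without-control-3 fits, against 10, 15 and 12 with the preset one. That test also has fewer degrees of freedom, so the loss does not measure correlation between genes alone. The 10 lists called in the unweighted fit had estimated correlations of 0.037 (contractile) to 0.592 (cholesterol), all above the preset 0.01. Those of the acinar, epithelial and proliferation lists were 0.038, 0.234 and 0.486. The preset test therefore assumed less correlation in these lists than was estimated. For the collagen list, which was not called, camera's unweighted adjusted p rose from 0.416 to 0.627, although its estimated correlation (0.0029) lay below the preset 0.01. Median and mean of the unweighted differences had opposite signs for the FGF (-0.16 and 0.02), immune (-0.05 and 0.02) and adipocyte (-0.23 and 0.11) lists.

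Among the genes of smallest p in the falling direction, Dusp10, a phosphatase of stress-activated kinases, fell by 1.34 ± 0.14 with array weights, Rrad, a small GTPase-related protein, by 1.28 ± 0.14, Enpep, an aminopeptidase, by 1.20 ± 0.15, Zfhx4, a homeobox factor, by 1.19 ± 0.20, Paqr8, a membrane progestin receptor, by 1.44 ± 0.18, and Hcn4, a cation channel, by 0.97 ± 0.13. Cdr2l fell by 0.96 ± 0.15 and Ptpdc1, a phosphatase, by 0.78 ± 0.14. Zfhx4 did not pass without control 3 and TGF-β1 3 (adjusted p = 0.0569). All 8 lay lower in each TGF-β1 array than in each control, and their adjusted p in the unweighted fit was 0.776.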

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

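The settings with control 3 and TGF-β1 3 both left out, and the list test with array weights, were chosen after the data were seen. The unweighted count of 0 genes stayed at 0 (limma) under quantile normalization (380 at an unadjusted p under 0.05), median centring (397), the filter on dim genes (295), the mean of probe sets (389), all probe sets (420), a trended and robust prior (333), both stricter thresholds, and with each array left out (0 to 0; 145 to 1487 at an unadjusted p under 0.05). It moved to 1342 with array weights, 505 with control 3 and TGF-β1 3 both left out, and 544 with array weights and control 3 left out. The deviations of same-numbered arrays from their group means correlated at -0.0662, -0.0078 and -0.0501. Control 3 enters every control deviation through that mean, so these values cannot show whether the replicate numbers pair the arrays. With the replicate block 0 genes passed in limma (322 at an unadjusted p under 0.05) and 11 lists in place of 10. Of the 10 lists, 0 passed with an estimated correlation and 0 with fry; the count was 8 to 14 with each array left out and 9 to 15 under the remaining alternatives.

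The median correlation of control 3 with the others was 0.587 and moved to 0.218 with dim genes left out. The first component's 81.9% moved to 90.7% on the 1000 genes of largest variance and to 56.0% with control 3 left out. Why these moved was not tested beyond the arrays and genes left out.

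Of 116 named genes of the comparison, 90 passed in the unweighted direction with array weights and 67 with both distant arrays left out; the smallest adjusted p of any named gene over the other settings lay between 0.0693 (without control 1) and 0.921. With control 3 left out 7 of these genes changed sign, and 2 to 5 with each other array left out. With array weights and with both arrays left out, the log2 differences turned to -0.39 and -0.30 for Tgfb1, -0.059 and -0.13 for Tgfb3, -0.49 and -0.54 for Tgfbr2, -0.36 and -0.33 for Snai2, -0.96 and -0.89 for Twist1, -1.91 and -1.83 for Ddit3, -0.49 and -0.59 for Krt5, -0.59 and -0.77 for Krt14, and -0.56 and -0.49 for Krt19; Tgfbr1 turned to -0.0036 with both left out. Quantile normalization turned Cdh2 to -0.066, Twist1 to -0.054, Ddit3 to -0.060 and Fgf10 to 0.084; the cause was not tested. With each array left out, the difference ranged from -1.75 to 0.70 for Cdkn1a, -0.036 to 0.54 for Tgfb1, -0.21 to 1.54 for Tgfbr1, -0.34 to 1.96 for Tgfbr2, -0.58 to 0.090 for Vim, -0.17 to 1.35 for Snai2, -0.58 to 0.47 for Twist1, -1.40 to 0.65 for Fgf10, -1.05 to 0.16 for Fgf7, -1.21 to 0.93 for Ddit3, -0.49 to 0.37 for Krt5, -0.22 to 1.36 for Krt14, -0.0052 to 1.40 for Krt19, -1.18 to 0.57 for Id3 and -0.75 to 0.50 for Cd34.

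Camera's direction also turned for lists, whose median log2 differences follow; a median can keep its sign where the direction turned. With array weights and with both arrays left out these were 0.062 and 0.041 (TGF-β ligands), -0.11 and -0.081 (collagens), -0.34 and -0.31 (collagen processing), 0.059 and 0.028 (basement membrane), -0.39 and -0.33 (mesenchymal transition), -0.097 and -0.041 (hypoxia), -0.51 and -0.49 (endoplasmic reticulum stress), -0.65 and -0.55 (interferon), -0.087 and -0.088 (Schwann cell), -0.31 and -0.32 (immune), 0.024 and 0.056 (skeletal muscle), 0.025 and 0.082 (cartilage), and -0.029 and -0.027 (adipocyte). With both left out the contractile (0.0002), FGF (0.066) and basal (-0.036) lists turned too. With dim genes left out the collagen (0.10), endoplasmic reticulum (0.32), interferon (-0.037), immune (-0.098) and adipocyte (-0.23) lists turned. Quantile normalization turned the mesenchymal transition (-0.054), endoplasmic reticulum (0.076), immune (-0.083) and adipocyte (-0.018) lists, the replicate block the FGF (-0.16) and immune (-0.046) lists, and fry the immune list (-0.046). The cause was not tested.

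With each array left out, the medians of the lists that turned ranged from -0.15 to 0.57 (TGF-β ligands), -0.18 to -0.018 (BMP), -0.11 to 0.28 (collagens), -0.075 to 0.45 (collagen processing), -0.37 to 0.034 (proteases), -0.15 to 0.70 (basement membrane), -0.28 to 0.47 (mesenchymal transition), -0.21 to -0.0033 (FGF), -0.43 to 0.76 (endoplasmic reticulum stress), -0.62 to 0.35 (interferon), 0.0014 to 0.80 (basal), -0.0014 to 0.56 (Schwann cell), -0.33 to 0.14 (endothelial), -0.43 to 0.13 (immune), -0.67 to 0.083 (skeletal muscle), -0.68 to -0.0036 (cartilage) and -0.43 to 0.13 (adipocyte). The acinar, epithelial, proliferation, cholesterol, neuron, p53, TGF-β target, inflammatory, immediate early, ductal and erythroid lists kept their direction under every setting run.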

Other observations

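The tests of explanations and the comparison of TGF-β1 3 with TGF-β1 1 and 2 were chosen after the results they bear on had been seen, while the array-weighted fit of the genes was planned. TGF-β1 3 held a programme that the other 2 TGF-β1 arrays did not show. All 27 measured interferon response genes were higher in TGF-β1 3 than in both TGF-β1 1 and 2, and 25 were higher than in controls 1 and 2 as well. Over all genes 40.3% were higher in TGF-β1 3 than in both. Trim30a, Rtp4 and Bst2, interferon-induced genes, were higher than the mean of the other 2 by 4.26, 3.76 and 3.22 log2 units, Usp18 and Irf7, regulators of the interferon response, by 2.85 and 2.59, and Isg15, an interferon-induced ubiquitin-like protein, by 2.48. The median over the interferon list was 1.37, and control 2 (Trim30a at 6.56) also exceeded control 1 (4.26). Krt17, a keratin of stressed and basal epithelium, was higher by 4.57, Lcn2, an iron-binding acute phase protein, by 4.46, Cxcl13, a B cell chemokine, by 4.55 and Apln, a ligand of endothelial cells, by 2.72. Fos and Egr1, immediate early transcription factors, differed by -2.83 and -1.84, and the immediate early list had a median of -0.48. These are values of 1 array, and the genes named here were chosen after their values were seen.

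Several genes outside the fixed lists also differed in the array-weighted fit. Among the genes that passed with non-overlapping groups, predicted genes left out, the 12 with the largest rise included Tspan1, a tetraspanin of secretory epithelia, with 3.17 ± 0.33 (SE), Acss1, a mitochondrial acetyl-CoA synthetase, with 3.01 ± 0.29, Padi2, a peptidylarginine deiminase, with 3.69 ± 0.35, and A2ml1, a protease inhibitor, with 3.85 ± 0.63 (adjusted p = 0.126 without control 3 and TGF-β1 3). The 12 with the largest fall among them included Trim66, a chromatin-associated protein, with -1.90 ± 0.21, Corin, a membrane protease, with -1.45 ± 0.26, Bdh2, a dehydrogenase, with -1.45 ± 0.15, and Aox1, an aldehyde oxidase, with -1.42 ± 0.22. Without control 3 and TGF-β1 3, Corin (adjusted p = 0.167) and Aox1 (0.0913) did not pass.

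The first pattern weighed is the distance of control 3 from the other arrays. Another sample with intact RNA would carry abundant ribosomal protein transcripts, but their median of 8.43 lay far below the 12.43 to 12.80 of the other arrays. Values listed beside the wrong probe sets would keep the spread of the column, but its interquartile range was 2.05 against 3.17 or more elsewhere. A weak or degraded target is a candidate explanation, since 5 of 5 housekeeping genes lay at least 1 log2 unit below the lowest of the other arrays. Some genes went the other way: Sox5 was at 10.87 in control 3 against 6.81 to 7.51 elsewhere, and Fn1 at 12.49 against 10.54 to 11.27. Loss of signal alone does not account for these 2 values, which were chosen after they were seen, and their cause was not tested. Probe positions misread before summarisation were not tested and stay open, and no biological explanation was tested.

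The second pattern is the interferon and immune programme of TGF-β1 3. A lower share of the main cell types would raise the markers of every other cell type alike. Among members above the median of TGF-β1 1 and 2, the upper quartiles of the Schwann cell and neuron lists were 0.76 and 0.66 (10 genes each). The lower quartile of the immune list was 1.19 there (9 genes). Over all members that quartile was 0.61. The upper quartiles of the skeletal muscle, Schwann cell and endothelial lists, at 0.84, 0.82 and 0.77, then lay above it. Over all members the immune list had a median of 1.04, and the endothelial, adipocyte and neuron lists had medians of 0.35, 0.28 and 0.14. The separation depends on a filter chosen after the data were seen, so this explanation stays open. More immune cells may account for part of it, since Pf4, Aif1 and Fcgr3, genes of myeloid cells, were higher by 2.90, 3.05 and 2.45. However, 3 of the 24 immune genes were not above both other arrays, and Ptprc and Csf1r, found on most leukocytes and on macrophages, were higher by 0.36 and 0.08 only. More immune cells and an interferon response of the gland's own cells cannot be told apart here, because 1 array carries the pattern.

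The third pattern is that 14 of 24 acinar and secretory markers rose and 10 of 27 TGF-β target genes fell with array weights in the arrays labelled TGF-β1. A larger share of epithelium as the whole cause of the secretory rise would move basal and myoepithelial markers by about as much, but with array weights their upper quartile was 0.41 and the median of the acinar list 1.15. The lower quartile of the acinar list was 0.08, so the 2 lists overlapped in part. No filter on dim members was applied here. Of the 18 basal members 12, and of the 24 acinar members 15, lay above the median of both TGF-β1 1 and 2. A larger share may account for part of it, since the lower quartile of the epithelial list was 0.45 and its upper quartile 0.92, and the mesenchymal transition list had a median of -0.39. Exchanged group labels would leave the feedback and direct target genes of TGF-β lower in the arrays labelled TGF-β1, and 1 of 6 was (Pmepa1, -0.75, adjusted p = 0.0360, but 0.07 unweighted, -0.41 without control 3 with an adjusted p of 0.916, and in TGF-β1 3 at 10.80, above all controls), while Smad7, Skil, Ldlrad4, Tgfbi and Ccn2 did not pass (-0.30, -0.63, 0.39, -0.29 and -0.17). In TGF-β1 1 and 2 Pmepa1 was at 9.68 and 9.48, below controls 1 and 2 (10.32 and 10.47), while control 3 was at 8.95. Correct and exchanged labels cannot be told apart from these values, since too few of the 6 passed in either direction.

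The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The unweighted fit called 0 genes in the real split and at most 0 in the others, so 10 of the 10 splits had as many. With array weights the real split called 1342 genes and the highest other 2308, and 2 of the 10 splits had as many as the real one. The highest other split set controls 1 and 2 with TGF-β1 3 against control 3 with TGF-β1 1 and 2, and its array weights were 0.0345 for control 3, 0.433 for TGF-β1 3 and 0.808 to 10.8 for the 4 others, which it parts as the real split does. The preset camera test called 10 lists in the real split and up to 18 in the others, and 9 of the 10 splits had as many.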
